A study of Mus musculus with 6 samples.

How the data were processed

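The series measured gene expression in NMuMG mouse mammary epithelial cells with 1-colour Affymetrix arrays, 2 arrays for each of 3 groups: control, TGF-β for 11 days, and TGF-β for 11 days followed by 13 days of withdrawal. Per the labels' protocols, total RNA was extracted with a column kit, and, with added poly-A control RNAs, made into biotin-labelled antisense RNA with the 3' IVT Express kit, which reads mainly the 3' end of transcripts. The deposited values are log2 expression per probe set, made with RMA per the submitters' processing notes. RMA corrects background, quantile normalises the arrays and summarises the probes of each set, so it sets the arrays to a common distribution and removes a shift shared by all genes. The software, its version and the arrays normalised together are not given in the sources used here. The 6 arrays had medians of 5.77 to 5.79. No scanner intensities or detection calls were used here, so a low value is not separated from background, and differences among dim genes are understated.

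The table holds 45101 probe sets. The 64 control probe sets were left out of all gene comparisons. The platform annotation gave 1 gene symbol to 34945 probe sets, several to 932 and none to 9160. Only those with 1 symbol were used, of which 34754 had a gene number in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed updating. The table served for names only, and no coordinates are given. Each of the 18193 genes was represented by the probe set with the highest mean over all 6 arrays, a choice blind to the groups; 9010 genes had several probe sets. Probe sets of a gene were called in opposite directions for Epcam, Zeb2, Rps9, Rps18 and H2-D1 among the genes considered.

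The analysis used limma 3.58.1 in R 4.3.3, with pandas 2.3.3 in Python 3.11.15 for the tables and matplotlib 3.10.9 for the figures. One linear model per gene was fitted to all 6 arrays with lmFit, without covariates, and its spread was moderated with eBayes (3 residual and 2.857 prior degrees of freedom). The 3 comparisons were TGF-β against control, withdrawal against TGF-β and withdrawal against control, each two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median standard error of a log2 difference was 0.0701, and the smallest differences called were 0.161, 0.151 and 0.149. A gene was counted as moving back when it was called under TGF-β and called in the opposite direction on withdrawal, and as still changed when both treated groups were called in the same direction from control. The remaining share is the withdrawal difference divided by the TGF-β difference, over genes called and changed by at least 1. For a single list it is taken over all members called under TGF-β, small changes included, so list shares are not directly comparable with it.

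Gene lists, 27 in all, covered responses known for TGF-β and for cell growth and stress, markers of other cell types, and technical groups. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. With an estimated correlation, camera rests on the 3 residual degrees of freedom, so a lost call need not come from correlated genes. The estimated correlation of the collagen list was -0.0049, below the preset value. Its unadjusted camera p under TGF-β still went from 6.27e-16 to 0.00264. Fry asks whether a list's genes move one way on balance, and does not set them against other genes. The median, mean and camera direction of a list differed in sign for 2 lists under TGF-β (other extracellular matrix, cytosolic ribosomal proteins), 6 on withdrawal against TGF-β (epithelial regulators, EMT transcription factors, BMP and Id genes, luminal markers, macrophage and leukocyte markers, immediate early and heat shock) and 7 for withdrawal against control (BMP and Id genes, other extracellular matrix, glycolysis and hypoxia, chromatin regulators, luminal markers, adipocyte markers, oxidative phosphorylation), and 0 of these passed in the comparison named.

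The groups, the tests, the lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 10 largest increases and decreases among called genes whose arrays do not overlap between the groups and whose higher mean lies in the upper part of all genes, with clone and predicted names left out; 22 marker genes, of which 21 were measured; up to 4 called members per list; and, for withdrawal against control, the 10 largest changes among genes also called under TGF-β and among those not called there. It named 241 genes, of which some are given. The alternative settings fixed at that time were the replicate number as a block, an intensity trend in the spread, leaving out the dimmest 40% of genes, the mean of probe sets per gene, leaving out probe sets whose names end in x, s or a, cyclic loess, quantile normalisation, a fit to the 2 groups compared, a floor at the 20th percentile, exchanged treated groups, stricter thresholds, counting probe sets, the other list tests, and each array left out in turn. Scaling to the poly-A and to the hybridization spikes was added after the control probe sets were seen, and the overlaps without a shared array after the overlaps were seen.

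The steps were tested on simulated data with 18193 genes and 6 arrays, with noise independent between genes. Few genes were changed, for TGF-β against control 70, 58 and 72 by 0.5, 1 and 2, besides the mitosis list. For TGF-β against control, 87.1%, 96.6% and 100% of genes changed by 0.5, 1 and 2 were recovered, with 11 false calls. For withdrawal against TGF-β the shares were 88.1%, 100% and 100%, with 12 false calls, and for withdrawal against control 89.6%, 100% and 100%, with 12. No recovered gene had the wrong sign. The data gave 5901 to 8235 calls per comparison, at a looser unadjusted p cutoff than in these sets. Their false calls can therefore be far more than 11 or 12.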

Results

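Expression was measured on 6 Affymetrix mouse arrays hybridised with RNA of NMuMG cells, an immortalised epithelial line from normal mouse mammary gland. Control cells received vehicle, a second group received 4 ng/ml of the cytokine TGF-β for 11 days, and the last group received the same treatment and was then kept without TGF-β for 13 days. Each group had 2 arrays, and their number limits the precision of every value. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The arrays of a group correlated at a Pearson's r of 0.998 over all probe sets, against 0.974 to 0.981 between groups, where probe sets are not independent replicates. The median absolute log2 difference within a group was 0.0784 to 0.0935, and between groups 0.152 to 0.209. Array medians lay between 5.77 and 5.79 on the log2 scale. The first principal component held 56.0% of the variance and separated the withdrawal arrays from the other 4, and the second held 39.6% and separated control from TGF-β.

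Another field of the labels gives the treated groups opposite state names, with the mesenchymal transition assigned to the withdrawal arrays and the epithelial transition to the TGF-β arrays. The groups used here follow the sample titles and the treatment entries. The contractile genes that TGF-β is known to induce were higher on the arrays titled TGF-β than on those titled withdrawal, with 24 of 32 members higher and 3 lower.

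The first comparison asked what 11 days of TGF-β changed in these epithelial cells. The smooth muscle genes Tagln and Acta2, which encode the actin-binding protein transgelin and smooth muscle α-actin, went from 6.91 ± 0.02 and 8.80 ± 0.0043 in control to 12.65 ± 0.056 and 13.62 ± 0.013 under TGF-β (log2, mean ± SD, n = 2). Cdh1, which encodes the adherens junction protein E-cadherin, fell from 11.94 ± 0.075 to 8.31 ± 0.081, and Ocln, which encodes the tight junction protein occludin, fell from 8.25 ± 0.30 to 4.96 ± 0.10. The collagen crosslinking enzyme gene Lox rose by 4.96 ± 0.057 (SE), and the transcriptional inhibitor gene Id2 fell by 5.38. In the limma test the adjusted p was 1.09e-06 for Tagln, 2.02e-06 for Cdh1, 2.82e-05 for Ocln, 1.09e-06 for Lox and 1.15e-06 for Id2.

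Of the other genes with the largest increases, Cxcl12, a chemokine gene, rose by 4.49, the myosin light chain gene Myl9 by 4.57, Ltbp2, which encodes a matrix protein of the latent TGF-β binding family, by 4.53, and Fstl1 by 4.39, with Klhl30 and Bnc2 at 4.63 and 4.47. Cldn4, a tight junction claudin gene, rose by 4.43, opposite to Cdh1 and Ocln. Among the largest decreases were the galectin genes Lgals4 at -5.57 and Lgals2 at -4.77, the tetraspanin gene Tspan8 at -5.28, the retinol carrier gene Rbp4 at -5.07 and the pantetheinase gene Vnn1 at -4.56. Serpina1b also fell, by 4.36, and is uncertain because the members of its family are nearly identical in sequence. These genes passed with adjusted p in the range 1.09e-06 to 4.25e-05.

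**Figure D1:**
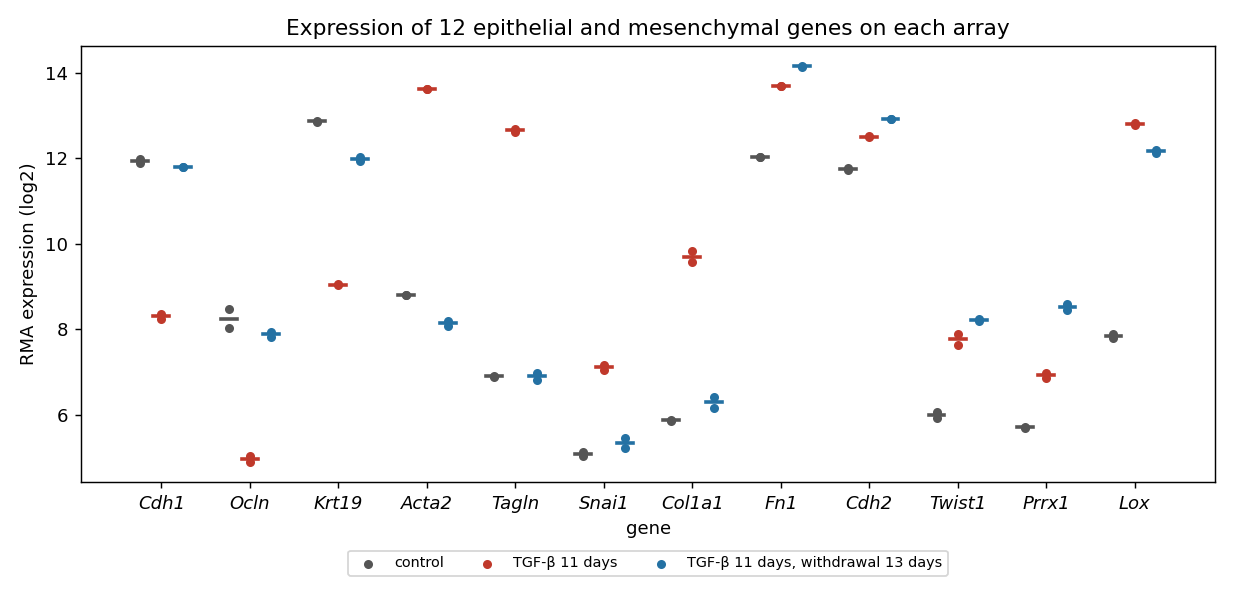
RMA expression (log2, vertical axis) of 12 genes on each array, with 2 points per group and a line at the group mean, for control, TGF-β for 11 days, and TGF-β for 11 days with 13 days of withdrawal. Cdh1, Tagln and Snai1 lay near control after withdrawal, at differences of -0.14, -0.0073 and 0.27, whereas Fn1, Twist1, Prrx1 and Lox lay 2.11, 2.23, 2.80 and 4.32 above it.

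Collagen, contractile and mesenchymal marker genes shifted up as lists. Of 33 measured collagen and collagen-modifying genes, 26 rose, 2 fell and 5 did not pass (27 and 2 called adjusted over the list alone). Col1a1, the α1 chain of type I collagen, rose by 3.83 ± 0.12 (SE), with Loxl1 at 3.45 and Col5a1 at 2.46. The collagen and collagen-modifying list passed camera upward at adjusted p = 1.69e-14, with adjusted p = 0.0452 with an estimated correlation. Of 32 measured actin and contractile genes, 24 rose, 4 fell and 4 did not pass (24 and 4 called adjusted over the list alone). They included the calponin gene Cnn1 at 2.80. The actin and contractile list passed camera upward at adjusted p = 9.63e-11, with adjusted p = 0.0452 with an estimated correlation. Of 27 measured mesenchymal adhesion and marker genes, 16 rose, 0 fell and 11 did not pass (16 and 0 called adjusted over the list alone). Among them were the growth factor receptor gene Pdgfrb at 4.32, the Wnt ligand gene Wnt5a at 3.15 and the matrix glycoprotein genes Thbs1 at 3.10, Tnc at 2.25 and Fn1 at 1.65. The mesenchymal adhesion and marker list passed camera upward at adjusted p = 3.10e-10, with adjusted p = 0.0452 with an estimated correlation. N-cadherin, encoded by Cdh2, rose by 0.75. The intermediate filament gene Vim rose by 0.39, and did not pass with spike scaling (adjusted p = 0.622 and 0.179).

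Of 22 measured EMT transcription factor genes, 13 rose, 3 fell and 6 did not pass (14 and 3 called adjusted over the list alone). They included Foxc2 at 2.49, Runx1 at 2.22, Snai1 at 2.04 and Twist1 at 1.77. The EMT transcription factor list passed camera upward at adjusted p = 1.09e-04, with adjusted p = 0.0883 with an estimated correlation. Zeb1 and Zeb2, which encode repressors of Cdh1, rose by 1.00 and 1.67, and Snai2 by 0.87.

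Of 34 measured TGF-β pathway and feedback genes, 21 rose, 3 fell and 10 did not pass (23 and 5 called adjusted over the list alone). The activin subunit gene Inhba was at 1.99, the receptor gene Tgfbr1 at -1.43 and the inhibitory Smad gene Smad7 at 0.57. The TGF-β pathway and feedback list passed camera upward at adjusted p = 4.98e-07, with adjusted p = 0.0581 with an estimated correlation. The difference of Tgfbi was 0.41 and did not pass limma (adjusted p = 0.0966), but did with an intensity trend and without the second control array (adjusted p = 0.0335 and 0.0402). Smad7 did not pass with poly-A scaling (adjusted p = 0.168). Of 18 BMP and Id genes, 4 passed upward and 5 downward (5 and 6 adjusted over the list alone; camera adjusted p = 0.762). The BMP and Id list passed downward with poly-A scaling and hybridization spike scaling (adjusted p = 0.00952 and 0.00968). Id1 was at -2.53, the ligand gene Bmp2 at -2.59 and the homeobox gene Msx2 at 2.20. Of 28 measured matrix protease and inhibitor genes, 10 rose, 4 fell and 14 did not pass (12 and 5 called adjusted over the list alone). Examples were Mmp13 at -3.80 and Adamts5 at 3.07, the inhibitor gene Timp3 at 3.38 and the urokinase gene Plau at 2.27. The matrix protease and inhibitor list passed camera upward at adjusted p = 0.036, with adjusted p = 0.213 with an estimated correlation. It lost its call without the first TGF-β array (adjusted p = 0.131) without the first withdrawal array (adjusted p = 0.0732) and without the dimmest 40% of genes (adjusted p = 0.0807). Of 27 other extracellular matrix genes, 5 passed upward and 5 downward (5 and 5 adjusted over the list alone; camera adjusted p = 0.867). Vcan was at 2.05 and Lamb3 at -1.77.

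Of 33 measured epithelial junction and polarity genes, 5 rose, 16 fell and 12 did not pass (5 and 17 called adjusted over the list alone). The desmoglein gene Dsg2 fell by 3.58. The epithelial junction and polarity list passed camera downward at adjusted p = 0.0165, with adjusted p = 0.226 with an estimated correlation. Epcam, at 0.19, and the splicing regulator gene Esrp1, at -0.24, did not pass, but did under 1 and 3 of the other settings. Of 13 keratin genes, 1 passed upward and 5 downward (1 and 5 adjusted over the list alone; camera adjusted p = 0.0991). The keratin list passed downward with the dimmest 40% of genes left out, poly-A scaling and hybridization spike scaling (adjusted p = 0.0234, 0.00216 and 0.00217). The keratin genes were Krt19 at -3.82, Krt8 at -0.73 and Krt18 at -0.53. Of 20 epithelial regulator genes, 3 passed upward and 6 downward (3 and 6 adjusted over the list alone; camera adjusted p = 0.277). The epithelial regulator list passed downward with the dimmest 40% of genes left out, poly-A scaling and hybridization spike scaling (adjusted p = 0.0429, 0.0183 and 0.0183). The protease inhibitor gene Spint2 was at -2.92 and Esrp2 at -1.73.

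Cell cycle genes were lower under TGF-β. Of 31 measured mitosis genes, 0 rose, 23 fell and 8 did not pass (0 and 25 called adjusted over the list alone). The cyclin gene Ccnb2 fell by 1.22. The mitosis list passed camera downward at adjusted p = 2.66e-09, with adjusted p = 0.137 with an estimated correlation. Of 34 measured MCM and DNA replication genes, 1 rose, 24 fell and 9 did not pass (2 and 25 called adjusted over the list alone). The clamp loader gene Rfc5 was at -0.86. The MCM and DNA replication list passed camera downward at adjusted p = 8.61e-07, with adjusted p = 0.0883 with an estimated correlation. Of 20 measured cholesterol biosynthesis genes, 1 rose, 13 fell and 6 did not pass (2 and 14 called adjusted over the list alone). Tm7sf2 was at -0.72. The cholesterol biosynthesis list passed camera downward at adjusted p = 0.00344, with adjusted p = 0.404 with an estimated correlation. Of 34 measured oxidative phosphorylation genes, 0 rose, 12 fell and 22 did not pass (0 and 13 called adjusted over the list alone). The succinate dehydrogenase gene Sdhd was at -0.50. The oxidative phosphorylation list passed camera downward at adjusted p = 0.00344, with adjusted p = 0.285 with an estimated correlation. Scaled to either set of spiked RNAs, the cholesterol and oxidative phosphorylation lists no longer passed (adjusted p = 0.172 and 0.244). Such scaling also adds the spike gaps between arrays of a group to the spread of every gene. List calls gained or lost with it need not reflect RNA level.

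Of 30 measured interferon response genes, 13 rose, 0 fell and 17 did not pass (14 and 0 called adjusted over the list alone). H2-K1 and H2-D1 were at 1.85 and 1.64, and are uncertain because these class I histocompatibility genes are closely similar. The interferon response list passed camera upward at adjusted p = 2.90e-05, with adjusted p = 0.142 with an estimated correlation. Of 23 measured unfolded protein response genes, 13 rose, 3 fell and 7 did not pass (14 and 3 called adjusted over the list alone). The transcription factor gene Xbp1 was at 0.82. The unfolded protein response list passed camera upward at adjusted p = 3.42e-04, with adjusted p = 0.0913 with an estimated correlation. Of 25 measured immediate early and heat shock genes, 13 rose, 3 fell and 9 did not pass (15 and 4 called adjusted over the list alone). Among them were Hspb1 at 2.80 and Jun at 1.60. The immediate early and heat shock list passed camera upward at adjusted p = 0.00422, with adjusted p = 0.226 with an estimated correlation.

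Of 20 measured basal and stem mammary marker genes, 2 rose, 7 fell and 11 did not pass (2 and 10 called adjusted over the list alone). Aldh1a1 was at -2.65 and the integrin gene Itga6 at -2.11. The basal and stem mammary marker list passed camera downward at adjusted p = 0.0175, with adjusted p = 0.338 with an estimated correlation. Of 16 luminal mammary marker genes, 1 passed upward and 3 downward (1 and 3 adjusted over the list alone; camera adjusted p = 0.485). The luminal mammary marker list passed downward with poly-A scaling and hybridization spike scaling (adjusted p = 0.0392 and 0.0394). The mucin gene Muc1 was at -3.69. Of 23 glycolysis and hypoxia genes, 5 passed upward and 8 downward (6 and 8 adjusted over the list alone; camera adjusted p = 0.853). Of 22 p53 target and apoptosis genes, 10 passed upward and 6 downward (10 and 7 adjusted over the list alone; camera adjusted p = 0.22). Of 33 chromatin and DNA methylation genes, 4 passed upward and 9 downward (4 and 11 adjusted over the list alone; camera adjusted p = 0.22). Of 19 macrophage and leukocyte marker genes, 0 passed upward and 1 downward (0 and 1 adjusted over the list alone; camera adjusted p = 0.762). The gene that passed was the mannose receptor gene Mrc1, at -2.83. Of 16 endothelial marker genes, 0 passed upward and 2 downward (0 and 1 adjusted over the list alone; camera adjusted p = 0.957). Of 14 adipocyte marker genes, 0 passed upward and 2 downward (0 and 2 adjusted over the list alone; camera adjusted p = 0.289). Pparg was at -1.17. Of 29 cytosolic ribosomal protein genes, 1 passed upward and 1 downward (1 and 0 adjusted over the list alone; camera adjusted p = 0.707).

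Over all 18193 genes, 2726 were higher and 3175 lower under TGF-β than in control by the limma test at the adjusted p threshold of 0.05, and 496 and 468 of them changed by at least 1 on the log2 scale. Of 27 lists 15 passed camera, 9 upward and 6 downward, and 3 passed with an estimated correlation, namely the collagen, contractile and mesenchymal lists. Scaling to poly-A spikes, RNAs added before labelling, moved the median of all genes to -0.30 and the split to 818 higher and 5334 lower, and scaling to hybridization spikes, added before hybridization, moved them to -0.17 and to 1319 and 4408, so changes are given relative to the arrays' common level. Under poly-A scaling the medians of the interferon, unfolded protein response and immediate early lists turned from 0.22, 0.24 and 0.25 to -0.068, -0.045 and -0.040, and that of the proteases from 0.080 to -0.21, and to -0.078 with hybridization spikes.

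The second comparison asked what changed when TGF-β was taken away for 13 days. By the labels, the withdrawn cells were also kept 13 days longer after treatment began, so days in culture and withdrawal cannot be told apart here. Cdh1 rose from 8.31 ± 0.081 to 11.80 ± 0.0086 and Ocln from 4.96 ± 0.10 to 7.89 ± 0.084 (log2, mean ± SD, n = 2), while Tagln fell to 6.90 ± 0.11 and Acta2 to 8.14 ± 0.087. The largest rise was that of Abca1, which encodes a transporter that exports cholesterol from cells, at 6.06 ± 0.086 (SE). Il11, a cytokine gene, and Has2, a hyaluronan synthase gene, fell by 5.76 and 4.73. In the limma test the adjusted p was 2.06e-06 for Cdh1, 6.52e-07 for Tagln and 1.01e-06 for Abca1.

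Lgals4 and Vnn1, which had fallen under TGF-β, rose by 5.83 and 5.37. The selenium transport gene Selenop rose by 4.84, the ceruloplasmin gene Cp by 4.76, the aminopeptidase gene Enpep by 5.09 and the sulfotransferase gene Sult1c2 by 5.70. Serpina1b and Serpina1c rose by 6.03 and 5.22, with the same uncertainty about near-identical relatives. The cyclooxygenase gene Ptgs2 fell by 3.79, the keratin gene Krt7 by 4.18, Ltbp2 by 3.81 and Myl9 by 3.55.

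Of 32 measured actin and contractile genes, 3 rose, 24 fell and 5 did not pass (3 and 26 called adjusted over the list alone). Cnn1 fell by 3.00. The actin and contractile list passed camera downward at adjusted p = 7.07e-07, with adjusted p = 0.117 with an estimated correlation. Of 33 measured epithelial junction and polarity genes, 15 rose, 8 fell and 10 did not pass (15 and 8 called adjusted over the list alone). Against the list's direction, Cldn4 fell by 2.19 and the plakophilin gene Pkp1 by 1.95. The epithelial junction and polarity list passed camera upward at adjusted p = 0.0432, with adjusted p = 0.415 with an estimated correlation. It lost its call without either withdrawal array or the first TGF-β array (adjusted p = 0.0576, 0.0571 and 0.0683). The call also ended without the dimmest 40% of genes, without probe sets ending in x, s or a, with cyclic loess and with a floor (adjusted p = 0.0957, 0.115, 0.059 and 0.0567). Its median of 0.13 turned to -0.085 under hybridization spike scaling. Of 31 measured mitosis genes, 0 rose, 31 fell and 0 did not pass (0 and 31 called adjusted over the list alone). The kinase genes were Aurka at -2.13, Aurkb at -1.93 and Cdk1 at -1.80. The mitosis list passed camera downward at adjusted p = 2.63e-17, with adjusted p = 0.147 with an estimated correlation. Of 34 measured MCM and DNA replication genes, 0 rose, 32 fell and 2 did not pass (0 and 33 called adjusted over the list alone). The licensing gene Cdc6 was at -2.32 and the cyclin gene Ccne2 at -2.21. The MCM and DNA replication list passed camera downward at adjusted p = 8.13e-15, with adjusted p = 0.117 with an estimated correlation.

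Of 23 measured unfolded protein response genes, 4 rose, 15 fell and 4 did not pass (4 and 15 called adjusted over the list alone). The asparagine synthetase gene Asns fell by 1.31. The unfolded protein response list passed camera downward at adjusted p = 0.016, with adjusted p = 0.328 with an estimated correlation. That call ended without probe sets ending in x, s or a (adjusted p = 0.115). Of 22 measured p53 target and apoptosis genes, 16 rose, 5 fell and 1 did not pass (16 and 5 called adjusted over the list alone). The desmosomal gene Perp was at 3.88 and Gadd45g at -3.28. The p53 target and apoptosis list passed camera upward at adjusted p = 0.0101, with adjusted p = 0.449 with an estimated correlation. Without the dimmest 40% of genes it had adjusted p = 0.0723. Of 34 measured oxidative phosphorylation genes, 16 rose, 2 fell and 16 did not pass (17 and 2 called adjusted over the list alone). Uqcrh was at 0.69. The oxidative phosphorylation list passed camera upward at adjusted p = 0.00304, with adjusted p = 0.415 with an estimated correlation. With either spike scaling it had adjusted p = 0.266, and its median of 0.16 turned to -0.063 with hybridization spikes.

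Of 33 measured collagen and collagen-modifying genes, 7 rose, 19 fell and 7 did not pass (7 and 19 called adjusted over the list alone). Col1a1 fell by 3.41, and the type VI collagen gene Col6a1 was at 1.84. The collagen and collagen-modifying list did not pass camera (adjusted p = 0.0869). The collagen and collagen-modifying list passed downward with probe sets ending in x, s or a left out (adjusted p = 0.0429). Of 34 measured TGF-β pathway and feedback genes, 8 rose, 17 fell and 9 did not pass (9 and 18 called adjusted over the list alone). Inhba, Ccn2 and Smad7 were at -2.34, -2.13 and -0.61. The TGF-β pathway and feedback list did not pass camera (adjusted p = 0.0869). The TGF-β pathway and feedback list passed downward with the mean of probe sets, poly-A scaling and hybridization spike scaling (adjusted p = 0.0384, 0.0169 and 0.0171). Of 27 measured mesenchymal adhesion and marker genes, 6 rose, 9 fell and 12 did not pass (7 and 9 called adjusted over the list alone). They divided, with Wnt5a at -3.16 and Itga5 at -1.48 against Pdgfrb at 1.07 and Fn1 at 0.46. The mesenchymal adhesion and marker list did not pass camera (adjusted p = 0.535). Of 22 measured EMT transcription factor genes, 9 rose, 7 fell and 6 did not pass (9 and 7 called adjusted over the list alone). Snai1 was at -1.77, against the homeobox gene Prrx1 at 1.59 and Twist1 at 0.46. The EMT transcription factor list did not pass camera (adjusted p = 0.713). Zeb2 was at -0.89, with another probe set of the gene called the other way. The call of Twist1 ended without the second withdrawal array and with hybridization spike scaling (adjusted p = 0.0512 and 0.106), and that of Fn1 with the latter (adjusted p = 0.115). Of 18 BMP and Id genes, 6 passed upward and 5 downward (6 and 5 adjusted over the list alone; camera adjusted p = 0.545). The BMP and Id list passed upward with poly-A scaling and hybridization spike scaling (adjusted p = 0.0191 and 0.0191). Id2 was at 3.98 and Bmp4 at 3.56.

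Of 13 keratin genes, 2 passed upward and 4 downward (2 and 4 adjusted over the list alone; camera adjusted p = 0.366). Krt19 was at 2.93. Of 20 epithelial regulator genes, 4 passed upward and 3 downward (4 and 2 adjusted over the list alone; camera adjusted p = 0.635). Of 27 other extracellular matrix genes, 8 passed upward and 7 downward (8 and 7 adjusted over the list alone; camera adjusted p = 0.489). Of 28 matrix protease and inhibitor genes, 11 passed upward and 7 downward (12 and 7 adjusted over the list alone; camera adjusted p = 0.339). Mmp13 was at 4.25. Of 20 cholesterol biosynthesis genes, 5 passed upward and 9 downward (6 and 9 adjusted over the list alone; camera adjusted p = 0.261). Of 23 glycolysis and hypoxia genes, 9 passed upward and 6 downward (9 and 6 adjusted over the list alone; camera adjusted p = 0.278). Of 30 interferon response genes, 6 passed upward and 1 downward (5 and 1 adjusted over the list alone; camera adjusted p = 0.307). Of 33 chromatin and DNA methylation genes, 15 passed upward and 7 downward (16 and 7 adjusted over the list alone; camera adjusted p = 0.161).

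Of 25 immediate early and heat shock genes, 9 passed upward and 12 downward (9 and 12 adjusted over the list alone; camera adjusted p = 0.84). The transcription factor genes Egr1 and Fos were at 4.24 and 2.76, and the small heat shock gene Hspb1 at -1.47. Of 16 luminal mammary marker genes, 2 passed upward and 1 downward (2 and 0 adjusted over the list alone; camera adjusted p = 0.684). Muc1 was at 3.49. Of 20 basal and stem mammary marker genes, 9 passed upward and 3 downward (9 and 3 adjusted over the list alone; camera adjusted p = 0.124). The basal and stem mammary marker list passed upward with the first TGF-β array left out (adjusted p = 0.0186). Of 19 macrophage and leukocyte marker genes, 2 passed upward and 0 downward (2 and 0 adjusted over the list alone; camera adjusted p = 0.912). Of 16 endothelial marker genes, 1 passed upward and 0 downward (1 and 0 adjusted over the list alone; camera adjusted p = 0.775). Of 14 adipocyte marker genes, 5 passed upward and 1 downward (5 and 1 adjusted over the list alone; camera adjusted p = 0.235). The adipocyte marker list passed upward with poly-A scaling and hybridization spike scaling (adjusted p = 0.0191 and 0.0191). The lipid droplet gene Plin4 was at 4.25. Of 29 cytosolic ribosomal protein genes, 5 passed upward and 0 downward (3 and 0 adjusted over the list alone; camera adjusted p = 0.339). The cytosolic ribosomal protein list passed upward with cyclic loess (adjusted p = 0.00537).

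In total 3960 genes were higher and 4023 lower after withdrawal than under TGF-β, 874 and 568 of them by at least 1, in the limma test. Of 27 lists 7 passed camera, 3 upward and 4 downward, and 0 with an estimated correlation, while 9154 genes had an unadjusted p under 0.05 and 24 lists passed fry, the other list test. Poly-A scaling moved the median of all genes to 0.12 and the split to 3506 higher and 1500 lower, and hybridization spike scaling to -0.25 and to 2146 and 7772.

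The last comparison asked how far cells after withdrawal differed from control cells. Fn1, which encodes fibronectin, was at 12.03 ± 0.0021 in control and 14.14 ± 0.024 after withdrawal (log2, mean ± SD, n = 2), Pdgfrb at 4.52 ± 0.14 and 9.91 ± 0.035, and Lox at 7.84 ± 0.064 and 12.16 ± 0.04. Abca1 was higher by 5.86 ± 0.086 (SE) and Krt7 was at -4.70. The differences of Cdh1, -0.14, Ocln, -0.36, Tagln, -0.0073, and Snai1, 0.27, did not pass, with limma adjusted p = 0.136, 0.0936, 0.946 and 0.0601, although Cdh1, Ocln and Snai1 passed under 2, 6 and 3 of the other settings. With hybridization spike scaling Tagln passed too, at -0.38 (limma adjusted p = 0.00634). The adjusted p was 3.90e-06 for Fn1, 2.22e-06 for Pdgfrb and 2.22e-06 for Abca1.

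Other large increases were those of the scavenger receptor gene Colec12 at 5.33, Eya4 at 5.03, Cxcl12 at 4.75, Mxra8 at 4.54 and Aebp1 at 4.47, genes that were also called higher under TGF-β. Plin4 at 4.10, the xanthine dehydrogenase gene Xdh at 4.01, the water channel gene Aqp5 at 3.93, the complement protease gene C1s1 at 3.88, Enpep at 4.99 and Pamr1 at 4.45 were higher after withdrawal and had an unadjusted p over 0.05 under TGF-β; whether the 2 responses differed was tested in the preceding comparison, where Abca1, Enpep and Plin4 passed. Among the decreases were Dsg2 at -2.73, the centriole kinase gene Plk4 at -2.53, Igfbp4 at -2.50 and Il11 at -2.54.

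Cell cycle genes lay below control. Of 31 measured mitosis genes, 0 were higher, 31 were lower and 0 did not pass (0 and 31 called adjusted over the list alone). They included Aurkb at -2.42 and Cenpe at -2.26 and the cyclin gene Ccna2 at -2.22. The mitosis list passed camera downward at adjusted p = 7.91e-19, with adjusted p = 0.131 with an estimated correlation. Of 34 measured MCM and DNA replication genes, 0 were higher, 33 were lower and 1 did not pass (0 and 34 called adjusted over the list alone). Cdc6 was at -2.75, Mcm5 at -2.09 and the ribonucleotide reductase gene Rrm2 at -2.07. The MCM and DNA replication list passed camera downward at adjusted p = 3.55e-17, with adjusted p = 0.072 with an estimated correlation. Of 22 measured p53 target and apoptosis genes, 16 were higher, 3 were lower and 3 did not pass (16 and 3 called adjusted over the list alone). The death receptor gene Fas was at 2.37, with Gadd45a at 2.20 and Perp at 2.57. The p53 target and apoptosis list passed camera upward at adjusted p = 1.04e-04, with adjusted p = 0.242 with an estimated correlation. Of 20 measured cholesterol biosynthesis genes, 1 was higher, 15 were lower and 4 did not pass (1 and 18 called adjusted over the list alone). Fdps was at -1.05 and Hmgcs1 at -0.78. The cholesterol biosynthesis list passed camera downward at adjusted p = 1.19e-04, with adjusted p = 0.355 with an estimated correlation. Control probe sets for 18S ribosomal RNA were higher by 0.96 after withdrawal than in control, and the hybridization spikes by 0.38.

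Of 33 measured collagen and collagen-modifying genes, 24 were higher, 1 was lower and 8 did not pass (24 and 1 called adjusted over the list alone). Loxl1 was at 4.61, Col8a1 at 3.55 and the procollagen processing gene Pcolce at 2.91. The collagen and collagen-modifying list passed camera upward at adjusted p = 2.05e-09, with adjusted p = 0.072 with an estimated correlation. Col1a1, at 0.42, passed limma (adjusted p = 0.0317). It lost its call without either control array or the first withdrawal array (adjusted p = 0.122, 0.100 and 0.131), and with the mean of probe sets (0.153). The replicate block, a floor on low values and both spike scalings ended it too (adjusted p = 0.0586, 0.0958, 0.219 and 0.775). Of 27 measured mesenchymal adhesion and marker genes, 14 were higher, 2 were lower and 11 did not pass (15 and 2 called adjusted over the list alone). Among them were Thbs1 at 3.00, Tnc at 2.44 and Cdh2 at 1.17. The mesenchymal adhesion and marker list passed camera upward at adjusted p = 2.54e-04, with adjusted p = 0.14 with an estimated correlation. Of 22 measured EMT transcription factor genes, 14 were higher, 4 were lower and 4 did not pass (15 and 4 called adjusted over the list alone). Examples were Prrx1 at 2.80, Twist1 at 2.23, Runx1 at 1.76 and Snai2 at 1.15. The EMT transcription factor list passed camera upward at adjusted p = 9.22e-04, with adjusted p = 0.151 with an estimated correlation.

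Of 28 measured matrix protease and inhibitor genes, 13 were higher, 4 were lower and 11 did not pass (14 and 4 called adjusted over the list alone). Adamts5 was at 4.15 and Adam8 at -2.46. The matrix protease and inhibitor list passed camera upward at adjusted p = 0.0186, with adjusted p = 0.211 with an estimated correlation. Without the first withdrawal array it had adjusted p = 0.0601. The medians of the mesenchymal and protease lists turned from 0.24 and 0.23 to -0.13 and -0.15 under hybridization spike scaling. Vim, at 0.16, passed limma (adjusted p = 0.0348), turned to -0.21 under that scaling and did not pass without any 1 of the 6 arrays. It also lost its call with the replicate block, quantile normalisation, a fit to the 2 groups and poly-A scaling (adjusted p = 0.059, 0.0707, 0.061 and 0.929).

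Of 13 measured keratin genes, 0 were higher, 8 were lower and 5 did not pass (0 and 9 called adjusted over the list alone). Examples were Krt20 at -2.18, Krt8 at -0.94 and Krt19 at -0.89. The keratin list passed camera downward at adjusted p = 0.00397, with adjusted p = 0.195 with an estimated correlation. Of 30 measured interferon response genes, 15 were higher, 1 was lower and 14 did not pass (15 and 1 called adjusted over the list alone). Ifit2 was at 1.72. The interferon response list passed camera upward at adjusted p = 2.54e-04, with adjusted p = 0.211 with an estimated correlation. Of 25 measured immediate early and heat shock genes, 13 were higher, 7 were lower and 5 did not pass (13 and 7 called adjusted over the list alone). Egr1 was at 4.39, Fos at 2.17 and the phosphatase gene Dusp1 at 2.11. The immediate early and heat shock list passed camera upward at adjusted p = 0.029, with adjusted p = 0.32 with an estimated correlation. It lost its call without the dimmest 40% of genes and with a floor on low values (adjusted p = 0.241 and 0.135).

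Of 32 actin and contractile genes, 14 passed upward and 9 downward (14 and 9 adjusted over the list alone; camera adjusted p = 0.144). The focal adhesion gene Vcl was at 1.10, Myl9 at 1.03 and Acta2 at -0.67. For Acta2 the value was -0.077 and did not pass without probe sets ending in x, s or a (adjusted p = 0.629). Of 34 TGF-β pathway and feedback genes, 17 passed upward and 8 downward (17 and 8 adjusted over the list alone; camera adjusted p = 0.0613). The TGF-β pathway and feedback list passed upward with cyclic loess (adjusted p = 0.043). The contractile median of 0.11 turned to -0.034 and -0.27 and the TGF-β pathway median of 0.19 to 0.045 and -0.19 under poly-A and hybridization spike scaling. Tgfbr2 was at 1.65, and the ligand genes Tgfb3 and Tgfb1 at 1.48 and 1.14. Of 33 epithelial junction and polarity genes, 6 passed upward and 10 downward (6 and 10 adjusted over the list alone; camera adjusted p = 0.568). Of 20 epithelial regulator genes, 1 passed upward and 5 downward (1 and 4 adjusted over the list alone; camera adjusted p = 0.181). Of 18 BMP and Id genes, 5 passed upward and 7 downward (5 and 7 adjusted over the list alone; camera adjusted p = 0.964). Of 27 other extracellular matrix genes, 8 passed upward and 5 downward (8 and 5 adjusted over the list alone; camera adjusted p = 0.365).

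Of 33 chromatin and DNA methylation genes, 13 passed upward and 11 downward (13 and 11 adjusted over the list alone; camera adjusted p = 0.568). The histone deacetylase gene Hdac9 was at 3.12, and the methyltransferase genes Dnmt1 and Ezh2 at -1.15 and -1.07. Of 23 glycolysis and hypoxia genes, 8 passed upward and 11 downward (8 and 11 adjusted over the list alone; camera adjusted p = 0.975). Of 23 unfolded protein response genes, 7 passed upward and 8 downward (7 and 8 adjusted over the list alone; camera adjusted p = 0.621). Of 16 luminal mammary marker genes, 1 passed upward and 3 downward (1 and 2 adjusted over the list alone; camera adjusted p = 0.982). Of 20 basal and stem mammary marker genes, 4 passed upward and 8 downward (4 and 9 adjusted over the list alone; camera adjusted p = 0.568). Of 19 macrophage and leukocyte marker genes, 1 passed upward and 2 downward (1 and 2 adjusted over the list alone; camera adjusted p = 0.664). Of 16 endothelial marker genes, 0 passed upward and 0 downward (0 and 0 adjusted over the list alone; camera adjusted p = 0.667). Vwf and Tek, at -0.36 and 0.27, did not pass limma (adjusted p = 0.0535 and 0.0591), but passed under 6 and 4 of the other settings. Of 14 adipocyte marker genes, 3 passed upward and 1 downward (3 and 1 adjusted over the list alone; camera adjusted p = 0.568). Of 29 cytosolic ribosomal protein genes, 8 passed upward and 1 downward (8 and 1 adjusted over the list alone; camera adjusted p = 0.181). The cytosolic ribosomal protein list passed upward with cyclic loess and a floor on low values (adjusted p = 0.00152 and 0.029). Of 34 oxidative phosphorylation genes, 12 passed upward and 10 downward (14 and 12 adjusted over the list alone; camera adjusted p = 0.568).

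By limma 3943 genes were higher and 4292 lower after withdrawal than in control, 920 and 634 of them by at least 1. Of 27 lists 11 passed camera, 7 upward and 4 downward, and 0 with an estimated correlation, while 9321 genes had an unadjusted p under 0.05 and 23 lists passed fry. Poly-A scaling moved the median of all genes to -0.18 and the split to 1967 higher and 3730 lower, and hybridization spike scaling to -0.42 and to 1655 and 12634. The time at which control cells were harvested is not given in the sources used here, so days in culture and treatment cannot be told apart in this comparison.

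**Figure D2:**
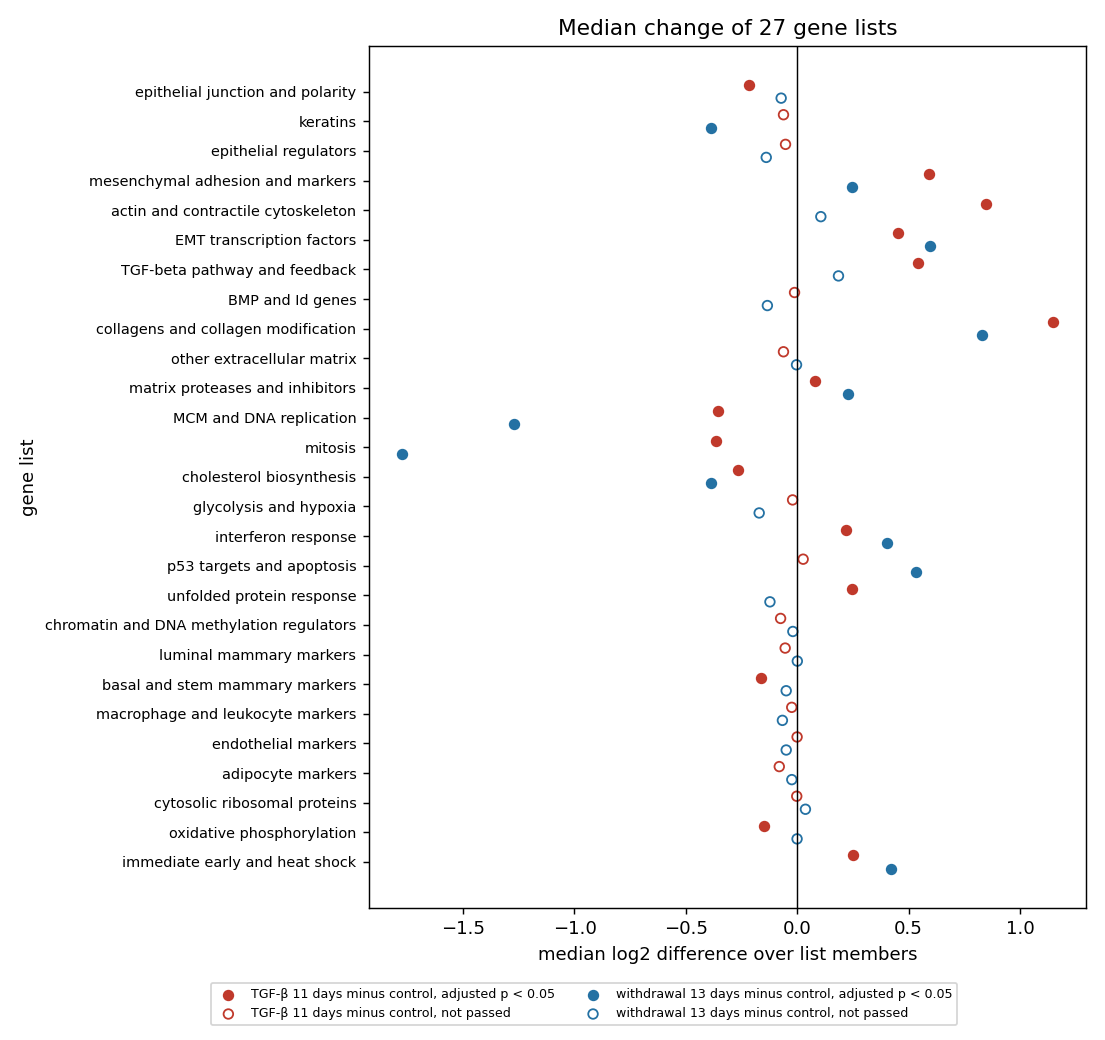
Median log2 difference (horizontal axis) over the measured members of each of 27 gene lists (vertical axis), for TGF-β against control in red and withdrawal against control in blue, with filled points for lists that passed camera. The collagen median was 1.15 under TGF-β and 0.83 after withdrawal, the contractile median 0.85 and 0.11, and the mitosis median -0.36 and -1.78; the contractile median after withdrawal turned to -0.034 and -0.27 under poly-A and hybridization spike scaling, and under at least 1 of them the positive medians of the protease, interferon, unfolded protein response, immediate early, mesenchymal, TGF-β pathway, p53, luminal and ribosomal protein lists turned negative in at least 1 of these comparisons.

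The 3 comparisons together show how far genes changed under TGF-β still differed from control after withdrawal. Days in culture run with the groups, so a difference in the TGF-β direction need not be a remainder of that response. Of the 28 contractile genes called under TGF-β, 26 moved back significantly and 15 stayed changed in the same direction from control. Their median remaining share of the change, taken for lists over all called members whatever the size of their change, was 0.175, where 0 is control and 1 the TGF-β level. Of 21 junction genes 19 moved back and 11 stayed changed, with a share of 0.242, and of 24 TGF-β pathway genes 18 and 13, with a share of 0.205. A gene that returned in part counts in both numbers. For EMT transcription factors 7 of 16 moved back and 14 stayed changed in the same direction from control, with a share of 1.09, for mesenchymal markers 6 of 16 and 13, with a share of 0.935, and for collagens 21 of 28 and 22, with a share of 0.591. Mitosis and replication genes moved farther from control, with 0 of 23 and 1 of 25 moving back and shares of 3.30 and 2.84.

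Of 5901 genes called under TGF-β, 2823 (47.8%) moved back after withdrawal and 3481 (59.0%) were still changed in the same direction from control. Independent lists of these sizes would share 1294 and 1340 genes. In 100 simulated sets of unchanged groups the overlaps were 0 and 0, because such sets give almost no calls, so they are no baseline for overlap among called genes. The comparisons with control share the 2 control arrays and the comparisons with TGF-β share its 2 arrays, so part of the excess over independent lists may come from shared controls and shared arrays. With 1 of the shared arrays given to each comparison, which was added after the overlaps were seen, 2092 of 4546 and 2073 of 4677 called genes moved back (46.0% and 44.3%; independent lists 853 and 865). In the same way 2442 of 4250 and 2460 of 4314 were still changed (57.5% and 57.0%; independent lists 790 and 795). The differences of the treated groups from separate control arrays correlated at 0.427 and 0.430. Of the genes that moved back, 1129 were no longer called against control, which does not show that they reached its level, 731 were still called in the same direction and 963 in the opposite one. Of the others, 1264 were called against control and not on withdrawal, 1486 moved significantly farther and 328 fell in no class. A further 2962 genes were called after withdrawal with an unadjusted p over 0.05 under TGF-β, 1347 higher and 1615 lower. Over all genes the log2 differences of both treated groups from control correlated at 0.447 (simulated 0.501), with a covariance of 0.141 against a simulated 0.00512, a difference of 0.136, where genes are not independent replicates. The sign was shared by 64.9% of genes, against 66.7% in simulation. The TGF-β and the withdrawal steps correlated at -0.427 (simulated -0.501), with a covariance of -0.133 against a simulated -0.00512, a difference of -0.128.

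Among the 964 genes changed by at least 1 under TGF-β the median remaining share was 0.465, with quartiles of 0.0840 and 0.859. The share was over 1 in 188 of these genes. With the control and TGF-β means held fixed, the SD of the median between the withdrawal arrays was 0.000742 (n = 2). Leaving out 1 array gave medians from 0.458 to 0.477, so that SD understates the spread of the value. The median remaining share was 0.654 for the 496 induced genes and 0.311 for the 468 repressed genes, a difference that was not tested. It depends on the arrays' common level, since a constant taken from all withdrawal values lowers the induced share and raises the repressed one. Hybridization spikes were higher than in control by 0.38 after withdrawal and 0.16 under TGF-β. The separate shares were not computed with spike scaling. The slope of the remaining on the initial change was 0.434, and 0.429 to 0.438 over 8 combinations of arrays, each with a different control array for the 2 differences. With the treated groups exchanged, as the other label field would have it, the share was 0.308 over 1554 genes. In that case 5443 of 8235 called genes moved back.

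**Figure D3:**
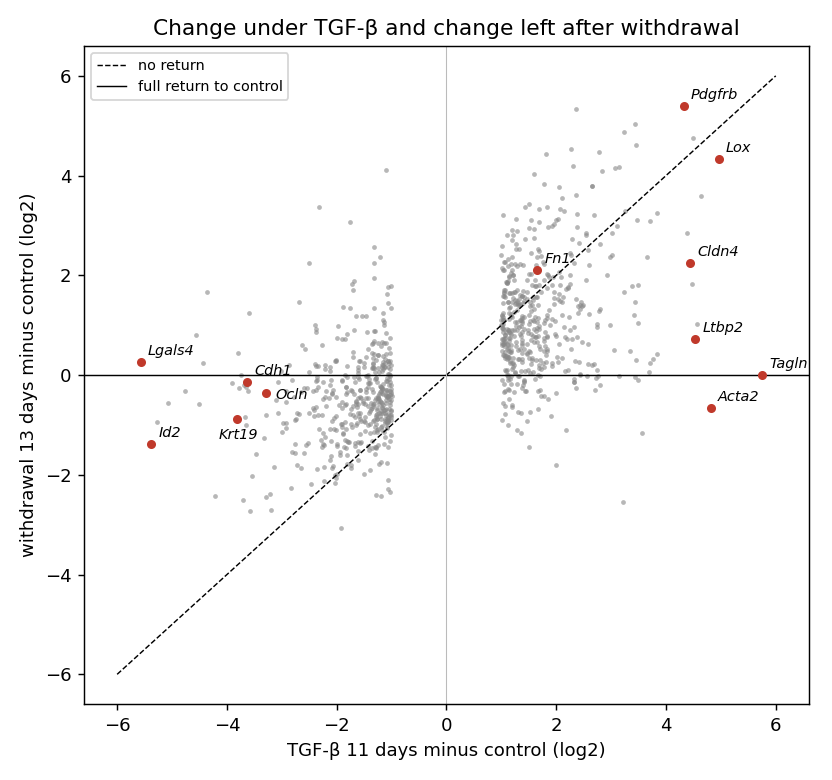
Log2 difference of the withdrawal group from control (vertical axis) against that of the TGF-β group from control (horizontal axis) for the 964 genes changed by at least 1 under TGF-β, 1 point per gene, with 12 named genes in red. Points on the solid line lie at the control mean, near which Tagln lay, at -0.0073, and points on the dashed line kept the full change; Pdgfrb, at 4.32 and then 5.40, lay above it.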

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

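The tests of exchanged arrays, of intensity bias, of a cell mixture and of continued signalling were chosen after the results were seen, and that of the next brightest probe set was chosen before its values were seen. The results given first come from probe sets that no gene comparison used.

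The 3 control probe sets for 18S ribosomal RNA were higher by a mean of 0.96 after withdrawal than in control, all 3 passing the limma test, against 0.14 and 0 passing under TGF-β. The 18 hybridization spike probe sets were higher by a mean of 0.38 after withdrawal, with 16 passing, against 0.16 and 0 passing under TGF-β. Of 9160 probe sets without a gene symbol, 307 were higher and 366 lower under TGF-β than in control, and 849 were higher and 706 lower after withdrawal.

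One field of the labels gives the TGF-β arrays the name of the epithelial transition and the withdrawal arrays that of the mesenchymal one, opposite to their treatment. An exchange of the treated arrays would put contractile genes higher in the group titled withdrawal. The median of the TGF-β minus the withdrawal group over that list was 0.75, with 24 of 32 members higher and 3 lower, which argues against an exchange. Where the names in that field come from was not tested.

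The withdrawal arrays lay farther from control than the TGF-β arrays, with 8235 against 5901 genes called, but with poly-A scaling the order turned, at 5697 against 6152, with hybridization spike scaling it stayed, at 14289 against 5727, and their correlations with control, which no constant per array can change, were 0.974 against 0.981. The poly-A spikes did not shift together after withdrawal, with dap probe sets at 0.41 to 0.60 from control and lys probe sets at -0.21 to 0.024. Their mean is thus an uncertain scale for these arrays. Intensity bias left by the normalisation is argued against as the whole account by cyclic loess, which gave 8132 and 5957. However, loess turned the withdrawal calls against control from 3943 higher and 4292 lower to 4302 and 3830. A part from intensity bias therefore stays open. Noise of single probe sets is argued against as the whole account by the next brightest probe set, whose sign was the same in 87.2% of the 3191 called genes where it was bright enough, though in less than the 93.3% of 2348 under TGF-β, so a part from noise stays open. Longer culture of the withdrawn cells, a different harvest density and a hybridization difference that acts unequally on genes stay open, since each runs with the groups. The 18S ribosomal RNA probe sets were also higher by 0.96 after withdrawal than in control. Whether the RNA put on these arrays differed in amount or quality was not tested. For a hybridization difference shared by all genes of an array, the spike-scaled counts decide nothing. The scaling itself moved the median of all genes to -0.42 with hybridization spikes. The lower correlations of the withdrawal arrays with control argue against such a shared difference as the whole account. A lasting effect of the treatment, the biological explanation that the design gives, stays open and untested beside them.

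Genes changed under TGF-β in part still differed from control after withdrawal, with a median remaining share of 0.465. The design cannot tell a retained response from an effect of longer culture in the same direction. If the cultures were only a mixture of returned and unreturned cells, each gene would lie between its control and its TGF-β level. However, 26.7% of the 964 genes (257) lay significantly outside, 133 beyond the TGF-β level and 124 beyond control. A mixture is thus not the whole account, though it may be part of it. Signalling that went on as under treatment is argued against by the TGF-β pathway list, where 75% of called members (18 of 24) turned back. Among all genes called under TGF-β, 47.8% did. However, 13 of the 24 were still changed in the same direction from control, and the list did not pass camera on withdrawal (adjusted p = 0.0869). These RNA levels do not measure signalling itself. A stable state distinct from both others, drift over passages and weaker signalling from the cells' own ligands stay open and were not tested.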

How the results depend on the processing

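All alternatives were planned before the data were examined except the 2 spike scalings, added after the control probe sets were seen, and the split of shared arrays, added after the overlaps were seen. Over all alternatives, named genes gave 6481 values on the same side of the threshold and in the same direction, 164 that lost and 35 that gained a call and 17 that reversed, and lists gave 1426, 51, 60 and 2. Named genes and lists under exchanged treated groups are left out, being exact swaps. The replicate numbers did not pair the arrays (correlations of deviations -0.0038, 0.0067 and -0.016), and the replicate block gave 5519, 7688 and 7908 calls, keeping 91.0%, 93.6% and 93.4%. Leaving out 1 array, where the lone array is assumed to vary like the others, kept each count within 1.5 times and gave remaining shares from 0.458 to 0.477. That share was 0.466 without the dimmest 40% of genes, 0.459 with the mean of probe sets, 0.469 with cyclic loess, 0.474 with quantile normalisation, 0.467 with a floor, 0.447 with poly-A scaling, 0.513 with hybridization spike scaling and 0.308 with exchanged groups, where 5443 of 8235 called genes moved back. The stricter thresholds lower counts by construction: with a change of at least 1, 496, 874 and 920 genes were higher, 468, 568 and 634 lower, 421 moved back and 369 stayed changed, and at an adjusted p of 0.01 1844 moved back and 2306 stayed changed. Counting probe sets, which tests more features, gave 4640, 6637 and 6781 higher and 4882, 7188 and 7464 lower. Cyclic loess gave 2799, 4308 and 4302 higher and 3158, 3619 and 3830 lower, so which direction held more calls after withdrawal depends on the normalisation. Lists past the threshold were 3, 0 and 0 with an estimated correlation, a test that rests on 3 residual degrees of freedom. With fry, which asks another question, they were 25, 24 and 23. With poly-A scaling 818 and 1967 genes were higher in the comparisons with control, 5334 lower under TGF-β and 1500 lower on withdrawal; with hybridization spikes 1319, 2146 and 1655 were higher in the 3 comparisons and 7772 lower on withdrawal against TGF-β and 12634 against control. A moved median of all genes does not account for all of these, since poly-A scaling lowered the calls of both directions in the comparisons of withdrawal. Which scaling is right was not tested, and the poly-A spikes did not shift together on the withdrawal arrays. Those of the control arrays themselves differed, at 8.68 and 8.38. Under scaling such gaps add to the spread of every gene, so gained and lost list calls need not reflect RNA level. Values that reversed on withdrawal against TGF-β were Rps9 (-0.19) and Rps18 (-0.034) with the mean of probe sets, and, without probe sets ending in x, s or a, Rps9 (-1.02), Rps18 (-0.40), Snai2 (-0.055) and Pnpla2 (-0.058). Without those probe sets Aldh1a3 reversed under TGF-β (-0.14), and against control after withdrawal Tnnt2 (0.046), Pnpla2 (-0.066), Rps18 (-0.16) and Rps9 (-0.60). Mmp9 reversed under TGF-β with poly-A scaling (-0.0036), and Vim (-0.21), Cd14 (-0.093), Pnpla2 (-0.033), Rps18 (-0.10) and Rps9 (-0.12) after withdrawal with hybridization spike scaling. With fry, glycolysis and hypoxia under TGF-β (mean -0.070) and immediate early genes on withdrawal (mean 0.23) reversed. Except where construction is named, the cause was not tested. Signal over background was not used here, so it is unknown which dim genes were detected.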

Other observations

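The tests of FoxO and YAP target genes were chosen after the results were seen, and that of liver X receptor target genes was chosen after Abca1 was seen but before the values of those genes were.

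Further genes with large changes are given here as values, and no list of them was tested. Ms4a4b, which encodes a membrane protein, rose on withdrawal by 4.83. After withdrawal against control the protease inhibitor gene Serpinb1a rose by 4.87 and Pzp, which encodes a broad-range protease inhibitor, by 3.32, and Ppp2r2b, a phosphatase regulatory subunit gene, by 2.89, with Ablim3, an actin-binding gene, at 3.67. Among the decreases on withdrawal were Bcat1, a branched-chain aminotransferase gene, at -3.59, and the collagen gene Col5a3 at -3.64. Each of these passed the limma test.

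Abca1 had the largest increase after withdrawal and is a known target of the liver X receptors, so a hypothesis was that targets of these receptors rose together. Over 20 further targets the median difference from control was -0.023, with 8 higher and 5 lower, a camera test that did not pass (adjusted p = 0.279, and adjusted p = 0.441 with an estimated correlation). The members went both ways around a median near 0, so the test neither bears out nor excludes a joint rise.

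Replication and mitosis genes were lower after withdrawal, and FoxO factors are known to act in quiescent cells, so a second hypothesis was that their targets rose. Over 23 members the median difference from control was 0.71, with 16 higher and 2 lower and camera adjusted p = 5.03e-06, but adjusted p = 0.235 with an estimated correlation, and 5 members belong to lists already tested. A rise of FoxO targets may go with the lower cell cycle genes. The setting with an estimated correlation rests on 3 residual degrees of freedom, so its result does not show that these genes are correlated. A shared response of correlated genes is not excluded either. Another hypothesis, that YAP targets, which are known to fall in crowded cells, fell together, was tested on 21 members. Their median was 0.45, with 13 higher and 5 lower, opposite to the prediction, and camera gave adjusted p = 0.0607 upward and adjusted p = 0.235 with an estimated correlation, with 3 members in lists already tested. Another 2 members, among them Ccn2, had been left out because the rule had named them, too few to turn the median below 0. The values therefore argue against a joint fall of these YAP targets, while a fall of single members is not excluded.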
